A study of Caenorhabditis elegans with 2 samples.

How the data were processed

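JUN-1, the worm Jun protein of the AP-1 family of basic leucine zipper (bZIP) transcription factors, was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole first-stage (L1) larvae of Caenorhabditis elegans. The labels describe the target as an eGFP-tagged jun-1 carried by a transgene in animals with an unc-119 mutation, mixed in sex. They give 2 biological replicates from separate biosamples, and these form the only group. The library size range in the labels is 150 to 350 bp.

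The authors deposited peak lists on the ce10 and ce11 assemblies. Each replicate has a list of peaks and background made as input for the irreproducible discovery rate procedure (IDR, which keeps peaks that rank alike in replicates). A further list of that kind was called on both replicates together, and an IDR-thresholded list was derived from the pooled and the replicate lists, per the deposited notes on file provenance. Those notes name 1 control alignment shared by both replicates, so part of the agreement between replicates may come from that control, and the lists do not allow the shares to be separated. The aligner, the peak caller, the IDR cutoff and the scaling of the signal are not given in the sources used here.

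The signal of each peak is the authors' own value in the deposited lists, and it was used only to describe, rank or filter peaks within a list. The deposited lists also give a −log10 q-value per peak. All IDR-thresholded peaks shared 1 value of it, 3.73, so peaks were ranked by the signal. Read counts are not part of the lists, so the depth of each library is unknown and no counting error of a single peak can be given. For a few peaks the signal in each replicate list is given as well, and the others are described by the signal of the IDR-thresholded list alone, with no error.

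The ce11 lists were the main data and the ce10 lists a check. Chromosome lengths of WBcel235, the assembly that ce11 names, held all peaks. Sequence came from the RefSeq copy of WBcel235 and genes from Ensembl release 115, with 19973 nuclear protein-coding genes. A peak was assigned to every protein-coding gene whose promoter window, 1000 bp upstream to 200 bp downstream of the annotated start, held its summit. Other summits were called exonic, intronic or intergenic from protein-coding gene models. A peak shared by promoter windows counts for each gene. Such an assignment records position and does not show regulation.

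Replicates were compared by the share of the 2305 strongest peaks of replicate 1 that overlapped one of the 2305 strongest of replicate 2 by at least 1 bp, against 1000 random placements within chromosomes. The promoter share was compared with 1000 random placements of the summits. Median signals were compared by permutation tests with 100000 resamples. Gene shares were compared by Fisher's exact test with Woolf intervals, adjusted by the Benjamini-Hochberg method over the 40 gene lists. Non-coding RNA lists were tested against all annotated nuclear genes and the others against protein-coding genes. Motifs were sought on both strands in the 200 bp window centred on the summit and in equal windows centred 500 bp to each side. An exact conditional test asked whether the summit window held the motif more often than 1 of 3 windows taken at random. The 10 panel motifs were adjusted by the Benjamini-Hochberg method, and all 2080 words of 6 bases by Bonferroni. Tests were two-sided, except those against random placements for overlap and for RNA genes. Peaks and genes are not independent replicates, so these p-values describe positions in 1 pair of libraries. Shares carry 95% Wilson intervals.

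The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule names jun-1, fos-1 and unc-119, and the 20 protein-coding genes with the strongest promoter peaks that a peak in each replicate list overlaps. It adds the 4 bound members with the strongest peaks of the bZIP, stress kinase and reported-target lists and of each list past the threshold. It also takes the 5 strongest peaks with an AP-1 or CRE element and the 3 strongest peaks outside promoter windows. Alternatives covered narrower and wider promoter windows, stricter peak and overlap rules, other backgrounds and motif windows, and each replicate alone, in which the 2305 strongest peaks of the other replicate replaced the IDR-thresholded list. Motif tests on autosomal peaks only and list tests without ribosomal protein genes were added after seeing the data.

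The statistics were tested on simulated data. With 2305 sets of windows and no implanted motif, 0 of the 6-base words passed the threshold and 1 of the 10 panel motifs had p under 0.05. All of these windows lay beside summits and were put in random order within each set. The check therefore does not cover differences in base composition between summit and flanking windows. Implanting an AP-1 element in 1% of peaks gave an exact conditional p = 0.00186, and in 3% p = 1.75e-12. With a true odds ratio of 3, the chaperone list was called in 58% of 50 draws, and with 5 in 94%. With bound genes drawn at random, 0.08 lists were called per draw. In these list simulations genes were drawn independently, whereas a real peak can count for more than 1 gene. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.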

Results

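JUN-1 binding was mapped by ChIP-seq in whole L1 larvae, in 2 biological replicates of 1 group. JUN-1 is the worm Jun protein, which pairs with other bZIP proteins to form AP-1 dimers. The data hold no second condition, so the comparisons are between the replicates, between peaks and the surrounding genome, and between genes with and without a peak. On the ce11 assembly the list of replicate 1 held 28101 peaks and that of replicate 2 held 30000, background peaks included. The list of replicate 2 also held 30000 on ce10, and such a round number may be a limit set on the list rather than the number of sites. The pooled list held 19646 and the IDR-thresholded list 2305, with a median signal of 44.7 and a range of 28.4 to 569. The read depth of the libraries is unknown. Of the IDR-thresholded peaks, 96.2% were 344 bp long.

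The replicates shared their strongest site. The first-ranked peak of each list lay at X:13700651-13701029, between genes, with a signal of 339 in replicate 1 and 230 in replicate 2. The strongest promoter peak of the IDR-thresholded list, at the ribosomal protein gene rpl-3, had a signal of 270 in replicate 1 and 184 in replicate 2. In replicate 2 the promoter peak of cebp-1 was stronger (186). Of the 2305 strongest peaks of replicate 1, 70.7% overlapped one of the 2305 strongest of replicate 2, against a mean of 1.60% and at most 2.47% in 1000 random placements (one-sided permutation p = 0.001, the smallest these allow). Among the IDR-thresholded peaks, 2293 were overlapped in both replicate lists, and 1619 (70.2%) were overlapped by the strongest 2305 of each. Across those 2293 peaks the signals had a Spearman rho of 0.616 (bootstrap interval 0.585 to 0.648) and a Pearson r of 0.708 on the log scale. This correlation is across peaks, which are not independent replicates. The IDR-thresholded list was made from both replicates, so the counts of 2293 and 1619 and the correlation are not free of that selection. Both replicates were called against the same control, so part of their agreement may come from it.

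**Figure D1:**
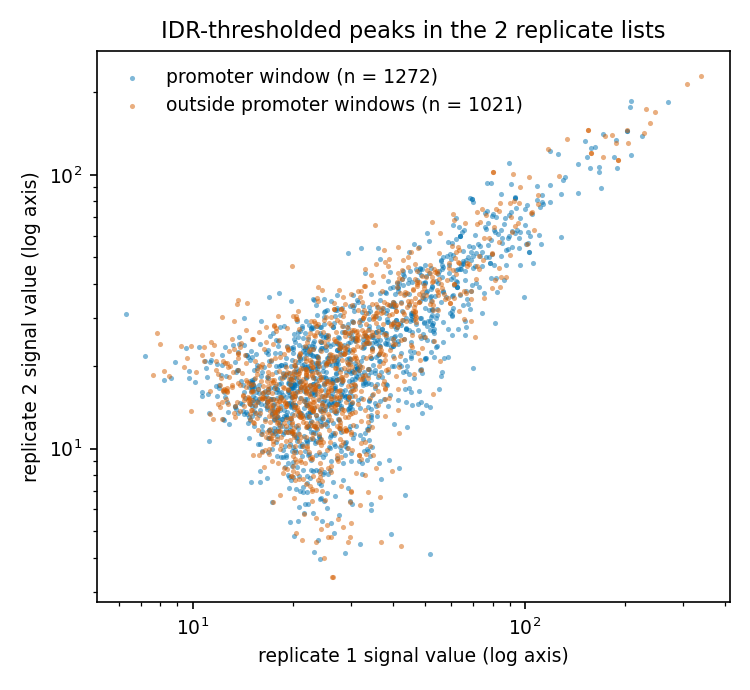
Signal of each IDR-thresholded peak in the list of replicate 1 (x axis) and replicate 2 (y axis), both on log axes, for the 2293 peaks overlapped in both lists, coloured by whether the summit lay in a promoter window. The strongest peaks lie together at the upper right, with 339 and 230 for the first.

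JUN-1 peaks lay mainly upstream of genes. Of the 2305 summits, 1278 (55.4%, Wilson interval 53.4% to 57.5%) fell in the promoter window of a protein-coding gene, against 21.2% of randomly placed summits (permutation p = 0.001, the smallest that 1000 placements allow). Exons outside promoter windows held 64 summits (2.78%), although they make up 23.1% of the genome. Introns held 414 (17.96%, against 30.4% of the genome) and intergenic sequence 549 (23.8%, against 25.04%). The median distance from a summit to the nearest gene start was 582 bp. In all, 1681 of 19973 protein-coding genes (8.42%) carried a promoter peak, and 408 peaks fell in the promoter windows of more than 1 gene. Promoter peaks had a higher median signal than other peaks, 46.4 against 42.4 (difference 3.95, permutation p = 0.00012). Among the stronger 1152 peaks the difference was 2.98 (permutation p = 0.175). It was 2.11 without replicate 1 and 1.40 without replicate 2, each on the scale of the replicate list left.

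The strongest promoter peaks were led by rpl-3, a protein of the large ribosomal subunit (peak III:3867458-3867695, summit 279 bp upstream, signal 455), and cebp-1, a C/EBP-type bZIP factor (X:1454463-1454765, 718 bp upstream, signal 393, with 209 in replicate 1 and 186 in replicate 2). A peak of signal 389 at III:10759130-10759378 lay between the divergent genes tasp-1, the worm taspase, and K01G5.10. Next came nspc-17 (363), the egg activation gene egg-5 (343) and cdc-48.1, an ATPase that extracts ubiquitinated proteins (II:10563477-10563679, 329). Then followed rpl-35 (322), the shared peak of nhl-2, a cofactor of microRNA silencing, and tag-340 (315), the Pumilio-family gene puf-9 (304) and the insulin-like gene ins-39 (296). The remaining genes of the 20 were the histone gene his-37 (296), iff-2, which codes for a translation factor, with F54C9.14 (285), tos-1 (278), the cytochrome oxidase gene cox-5A (274), rpl-20 with Y17G9B.5 (274) and the F-box gene fbxb-58 (268).

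Among the 40 gene lists, 13 were enriched for promoter peaks and 5 depleted. Ribosomal protein genes stood out, with 59 of 78 bound (75.6%, Wilson interval 65.1% to 83.8%) against 8.15% of other protein-coding genes (odds ratio 35.0, interval 20.8 to 58.8, adjusted p = 4.09e-46 by Fisher's exact test). Their strongest peaks were at rpl-3, rpl-35, rpl-20 and rpl-15 (262). When each summit was given only to its nearest gene start, their odds ratio was 12.4. The proteasome, which degrades ubiquitinated proteins, had 14 of 33 genes bound (odds ratio 8.08, adjusted exact p = 1.20e-06), among them rpn-3 (125), rpn-11 (62.0), pbs-1 (55.9) and rpt-2 (49.4). Of the unfolded protein response genes of the endoplasmic reticulum, 10 of 20 were bound (odds ratio 10.9, adjusted exact p = 8.35e-06), led by cdc-48.1, the BiP-type chaperone gene hsp-3 (171), xbp-1 (134) and pdi-3 (113). Chaperones had 19 of 63 genes bound (odds ratio 4.74, adjusted exact p = 3.80e-06), with hsp-60 (200), cct-8 (193), hsp-3 and cct-1 (165) in front. The peaks of hsp-60, cct-8 and cct-1 lay nearer the starts of Y22D7AL.10, Y55F3AR.2 and mig-5, and that of pdi-3 nearer ubql-1. With each summit given only to its nearest gene start, the call for chaperones ended (odds ratio 2.17, adjusted exact p = 0.134). Cell cycle and replication genes had 15 of 47 bound (odds ratio 5.14, adjusted exact p = 2.00e-05), including pcn-1 (112.4), the worm PCNA, cdk-5 (93.4), the E2F-type gene efl-1 (88.1) and lin-35 (63.5), the worm retinoblastoma gene, whose peak lay nearer the start of vps-51.

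Genes of the lysosome, of developmental timing and of some classes of non-coding RNA were enriched too. The calls for the autophagy, heterochronic and microRNA lists each ended under an alternative given in the next paragraph. The autophagy and lysosome list had 11 of 54 genes bound (odds ratio 2.80, adjusted exact p = 0.0130), with lgg-2 (148), epg-7 (148), lgg-1 (127) and cpr-3 (66.2) strongest. Of the subunits of the vacuolar proton pump, 6 of 20 were bound (odds ratio 4.68, adjusted exact p = 0.0130), led by vha-8 (108, nearer the start of C17H12.2), vha-12 (97.47), vha-15 (59.9) and vha-1 (55.6). The heterochronic list, which times larval fates, had 5 of 18 bound (odds ratio 4.19, adjusted exact p = 0.0316), namely nhl-2, ain-1 (174), lin-66 (90.01), lin-14 (51.2) and, named after its value was seen, lin-28. Against all annotated genes, snoRNA genes had 111 of 346 bound (odds ratio 7.81, adjusted exact p = 1.75e-49) and tRNA genes 130 of 612 (odds ratio 4.47, adjusted exact p = 9.48e-37). The snRNA genes had 18 of 129 bound (13.95%, odds ratio 2.60, adjusted exact p = 0.00212) and microRNA genes 31 of 261 (11.9%, odds ratio 2.16, adjusted exact p = 0.00114). In these RNA tests 5.69% to 5.87% of the other annotated genes were bound, a lower share than the 8.42% of protein-coding genes. The RNA lists were not tested against protein-coding genes. Some peaks at RNA genes also lay in a coding promoter window, as 55.4% of all IDR-thresholded peaks did. These were 53 of the 107 peaks at snoRNA genes, 24 of the 111 at tRNA genes, 12 of the 19 at snRNA genes and 4 of the 26 at microRNA genes.

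Promoter peaks were depleted in 5 lists. Chemoreceptor genes had 16 of 1309 bound (1.22%, odds ratio 0.126, adjusted exact p = 8.56e-31), the strongest being srz-62 (176), sri-5 (76.4), srh-16 (72.7) and srr-10 (52.9, nearer the start of clic-1). F-box genes had 12 of 322 bound (odds ratio 0.417, adjusted exact p = 0.00373), with fbxb-58, fbxb-85 (142), fbxc-29 (129) and fbxa-90, which shares the peak of efl-1, strongest. Neuropeptide and insulin-like genes had 3 of 140 bound (odds ratio 0.237, adjusted exact p = 0.0104), which were ins-39, nlp-31 and nlp-34. The last 2 share a peak of signal 34.1 and are also counted in the antimicrobial list. The odds ratio of neuropeptide and insulin-like genes was 0.0824 without replicate 1. Cuticle collagens had 5 of 175 bound (odds ratio 0.318, adjusted exact p = 0.0140), namely col-38 (79.0, nearer the start of rpl-5), col-71 (36.8, nearer Y49F6B.2), col-185 (33.9, with 12.3 in replicate 1 and 21.97 in replicate 2), col-63 (32.9) and, named after its value was seen, col-8. C-type lectins had 9 of 240 bound (odds ratio 0.421, adjusted exact p = 0.0157), with clec-78 (201), clec-72 (71.2), clec-241 (49.4, nearer clc-13) and clec-170 (45.7, with 33.7 in replicate 1 and 9.77 in replicate 2) strongest. When each summit was given only to its nearest gene start, the adjusted exact p rose to 0.134 for chaperones (odds ratio 2.17), microRNA genes (1.71) and C-type lectins (0.509), to 0.0741 for F-box genes (0.521) and to 0.0678 for heterochronic genes (4.25). The call also ended for C-type lectins without replicate 2 (odds ratio 0.510, adjusted exact p = 0.0589), for the autophagy list among the stronger 1152 peaks (2.06, p = 0.211), for heterochronic genes in the narrower promoter window (1.77, p = 0.560) and, in a Mantel-Haenszel test stratified by upstream distance, for neuropeptides (0.298, p = 0.0605).

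**Figure D2:**
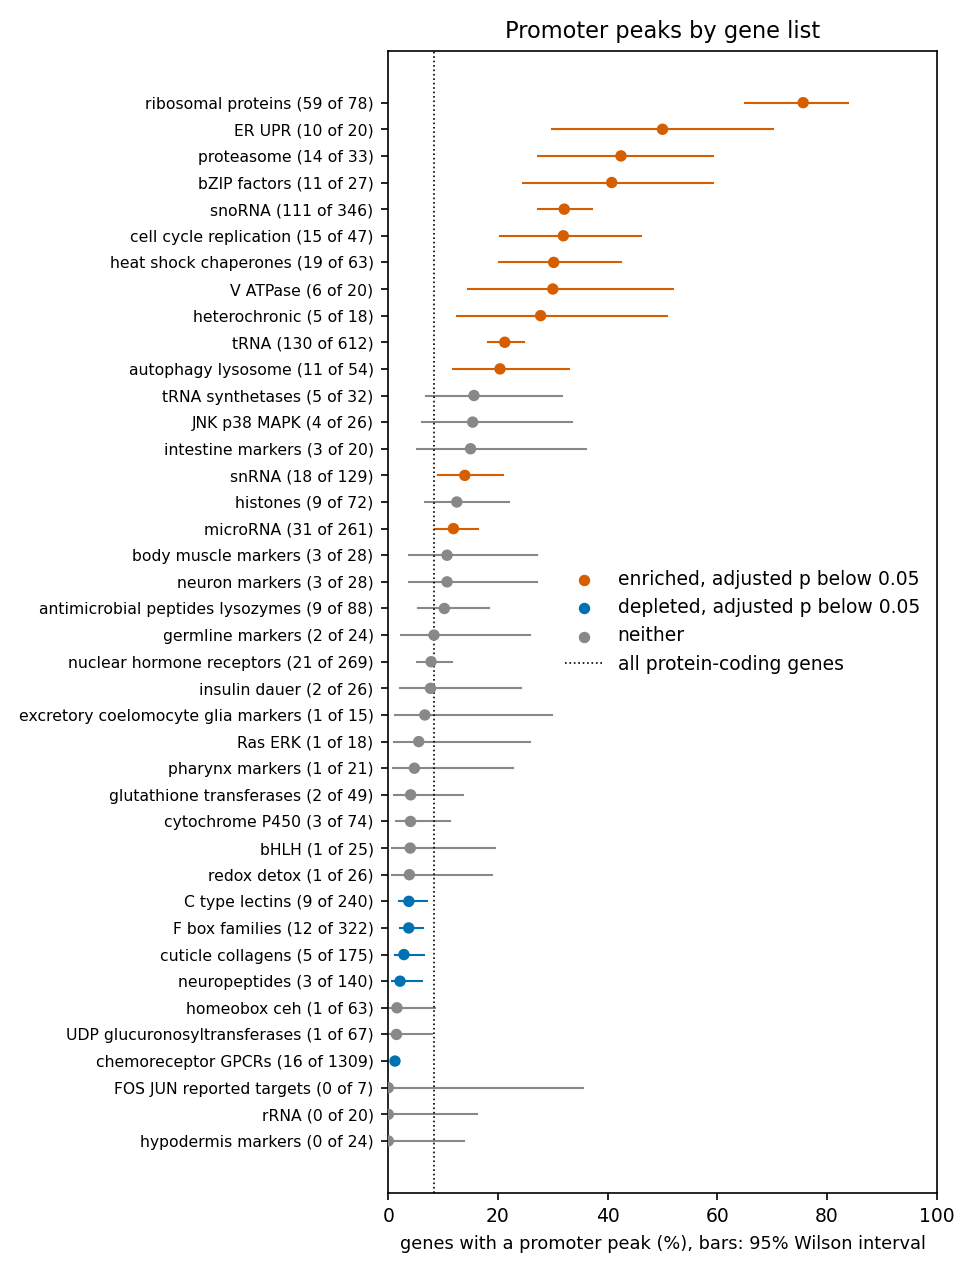
Percentage of genes with a promoter peak in each of the 40 lists (x axis), with 95% Wilson intervals as bars and bound and total genes beside each name; colours mark lists past the adjusted threshold and the dotted line marks all protein-coding genes (8.42%), although RNA lists were tested against all annotated genes. Ribosomal protein genes reach 75.6% and chemoreceptor genes lie at 1.22%.

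bZIP factors, the family of JUN-1 itself, had peaks at 11 of 27 members (40.7%, odds ratio 7.52, interval 3.49 to 16.2, adjusted exact p = 2.37e-05). The strongest were at cebp-1, at xbp-1, the bZIP factor of the unfolded protein response (III:4193618-4193961, 19 bp upstream, with 1 CRE element in the summit window), at zip-4 (76.6) and at atf-6 (63.2). The odds ratio was 3.75 without replicate 2 (adjusted exact p = 0.0170). In the list of JNK and p38 stress kinase genes, 4 of 26 members were bound (odds ratio 1.98, adjusted exact p = 0.419, and 0.564 in the narrower promoter window). These were unc-16 (68.4), a kinase scaffold, kgb-1 (53.1, nearer the start of T07A9.12), a JNK-like kinase, mlk-1 (38.3) and vhp-1 (28.6), a phosphatase of stress kinases. None of the 7 genes written down as reported targets of FOS-1 or JUN-1 had a promoter peak (Wilson interval 0% to 35.4%). With 8.42% of other protein-coding genes bound, a list this short cannot show a difference.

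The jun-1 gene itself (II:9113157-9132231) had no peak within 1 kb in any of the 4 lists, where the chromosome's average rate would give 5.75 in replicate 1 and 6.13 in replicate 2. The stretch without peaks ran from II:9099430 to 9139029 in replicate 2. Over the replicate and pooled lists its left end differed by 75 bp and its right end by 22 bp. fos-1, the gene of the usual AP-1 partner (V:6003601-6016087), had no IDR-thresholded peak either, but 14 peaks of replicate 1 and 12 of replicate 2 lay within 1 kb of it, with signals up to 13.2 and 9.71. The nearest IDR-thresholded peak was 3060 bp from its start (V:6000369-6000712, signal 149). unc-119 (III:10902641-10908935), which is mutated in the strain, had no IDR-thresholded peak, and 7 and 3 peaks in the replicate lists.

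**Figure D3:**
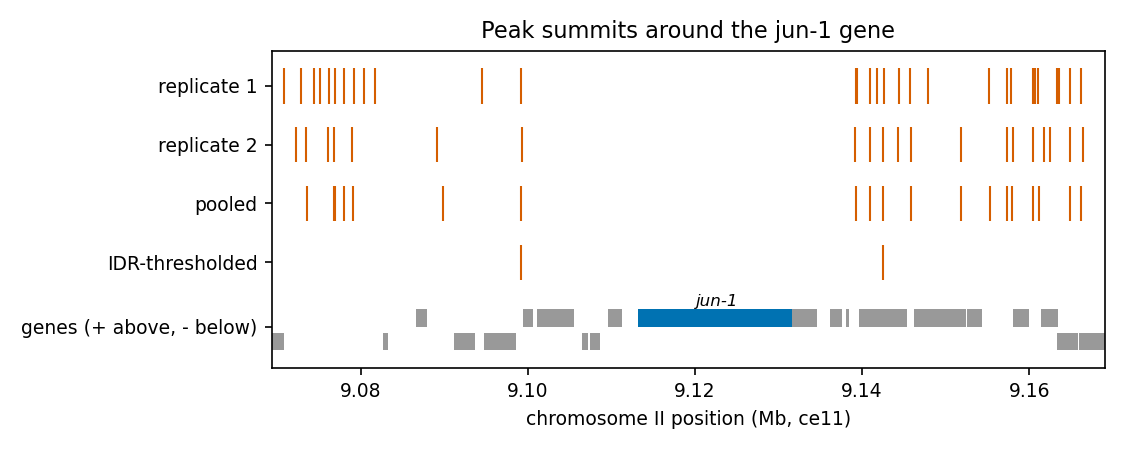
Peak summits (vertical ticks) of the replicate, pooled and IDR-thresholded lists around jun-1 on chromosome II (x axis, Mb on ce11), above protein-coding genes drawn to scale by strand, jun-1 in blue. The replicate and pooled lists hold no summit between the positions 9099430 and 9139029, and hold peaks on both sides.

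Over the chromosomes, X-linked and autosomal genes did not differ past the threshold in the share with a promoter peak, 228 of 2731 (8.35%) against 1453 of 17242 (8.43%; odds ratio 0.990, interval 0.856 to 1.15, Fisher's exact p = 0.911). Stratified by the distance to the nearest upstream gene, the X-linked odds ratio was 1.18 (Mantel-Haenszel chi-square p = 0.0288), and without replicate 1 the unstratified odds ratio was 1.03, so the direction depended on these choices. The 10 strongest sites outside promoters lay on X. The first 3 were X:13700651-13701029 (signal 569, 6045 bp from the start of K02D3.1), X:11093959-11094397 (522, 3993 bp from W02H3.3) and X:4209107-4209455 (413, 1784 bp from F20B6.9), all intergenic. Of the 20 strongest peaks outside promoters 14 were on X, which held 23.2% of all such peaks. Genes in the central 50% of the autosomes were bound more often than those on the arms, 868 of 9597 (9.04%) against 585 of 7645 (7.65%; odds ratio 1.20, interval 1.08 to 1.34, Fisher's exact p = 0.00112). Among the stronger 1152 peaks this odds ratio was 1.15 (Fisher's exact p = 0.0538).

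**Figure D4:**
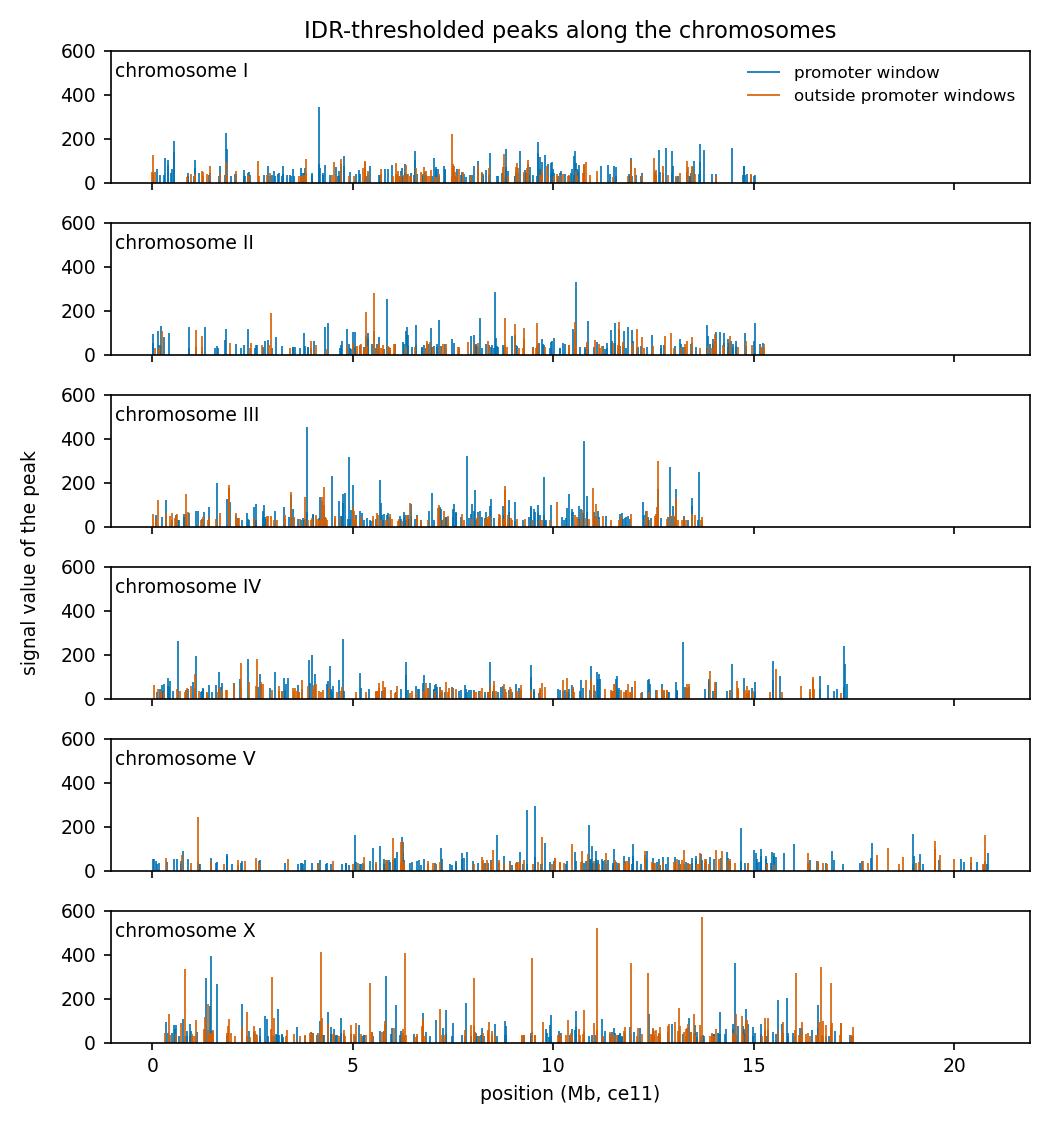
Signal (y axis) and position (x axis, Mb on ce11) of the 2305 IDR-thresholded peaks on each chromosome, coloured by whether the summit lay in a promoter window. The tallest lines outside promoter windows are on X, up to a signal of 569.

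The AP-1 element TGASTCA, where S is C or G, was found in 113 of 2305 summit windows (4.90%, Wilson interval 4.09% to 5.86%) against 2.10% of the windows 500 bp away (2.33-fold, exact conditional p = 4.76e-10). The related CRE element TGACGTCA, which Jun and ATF dimers bind, was in 35 windows (1.52%) against 1.13% (1.35-fold, exact conditional p = 0.211). Its excess passed the threshold without replicate 1 (2.00-fold, exact p = 0.00179) and against shuffled windows or windows near genes without a peak. Some other elements were commoner at the summits. CTGCGTCTC, a recurrent worm promoter element, was in 15.3% of summit windows against 0.846% (18.1-fold, adjusted exact p = 1.23e-125), and GAGAGAGA in 13.4% against 1.34% (9.94-fold, adjusted exact p = 9.12e-91). The E-box CACGTG was in 7.90% against 3.86% (2.04-fold, adjusted exact p = 1.63e-11) and the forkhead element TGTTTAC in 3.90% against 2.23% (1.75-fold, adjusted exact p = 0.000238). The GATA element TGATAA showed 20.3% against 18.03% (1.13-fold, adjusted exact p = 0.0289). Among the stronger 1152 peaks it was 0.832-fold, past the threshold in the other direction (adjusted exact p = 0.0439). Against shuffled windows it was 1.91-fold (adjusted exact p = 1.14e-41), and the call ended in 400 bp windows and against windows near genes without a peak. That of TGTTTAC ended among the stronger 1152 peaks (1.48-fold), and that of CCAAT in 400 bp windows (0.964-fold) and against shuffled windows (0.978-fold). The heat shock element TTCNNGAA (0.553-fold, adjusted exact p = 1.22e-13) and CCAAT (0.865-fold, adjusted exact p = 0.000238) were rarer at the summits than beside them. Against shuffled windows TTCNNGAA was 0.795-fold (adjusted exact p = 0.00183). The SKN-1 core TGTCAT did not differ past the threshold (1.02-fold, adjusted exact p = 0.804), but was rarer than in shuffled windows (0.842-fold, adjusted exact p = 0.00590). Of all 2080 words of 6 bases, 471 were enriched and 382 depleted after Bonferroni correction. This scan was run only against the flanking windows, so it does not separate single words from base composition. GAGAGA, with the smallest p, was in 42.7% of summit windows against 9.93%, and ACGCAG, the reverse complement of the first 6 bases of CTGCGTCTC, was in 26.2% against 3.97%.

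**Figure D5:**
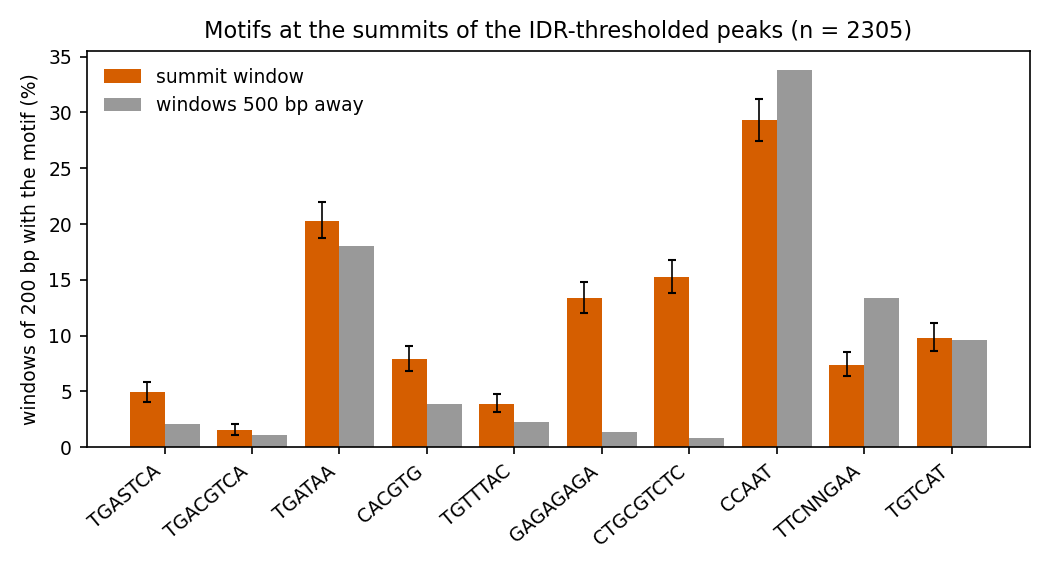
Percentage of 200 bp windows with each panel motif (y axis) at the summits of the 2305 IDR-thresholded peaks, with 95% Wilson intervals, and in the windows 500 bp to either side. CTGCGTCTC reaches 15.3% against 0.846% and TGASTCA 4.90% against 2.10%.

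The 143 peaks with an AP-1 or CRE element did not differ in signal from the rest past the threshold. Their median was 43.9 against 44.8 for the 2162 others (permutation p = 0.672), and without replicate 2 the difference turned to 0.330. The strongest of them lay at cebp-1, followed by an intronic site of vhp-1 (II:5337016-5337101, signal 194, with 103 in replicate 1 and 98.2 in replicate 2). The next were at the chemoreceptor gene srz-62, at vps-60 (V:8606431-8606533, signal 162), which codes for a membrane-trafficking protein and had 1 copy of each element, and at Y18D10A.4 (157).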

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

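Some pooled peaks with the top −log10 q-value were outside the comparisons of the report. Of the 2666 pooled peaks at the top −log10 q-value of 3.73, 361 were not in the IDR-thresholded list. That value is the highest in the list and is shared by all of them, so it does not rank them. The IDR-thresholded list held the 2305 strongest pooled peaks, with a lowest signal of 28.4.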

How the results depend on the processing

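The motif tests on autosomal peaks and the list tests without ribosomal protein genes were chosen after seeing the data. Of 83 alternatives to results that answer a comparison, 71 were counted as the same. For tests this means the same direction and side of the threshold. For counts it means within 1.5 times, whichever single lists, motifs or words passed. For the rank correlation it means within the bootstrap interval of the main value. The replicate overlap (46.4% to 75.8%), the promoter share (45.4% to 71.4%), the number of enriched lists (10 to 13), the TGASTCA excess (1.42-fold to 2.87-fold), the panel count (6 to 9) and the enriched 6-base words (356 to 471) did so under all alternatives run. Random placements gave a mean of 18.95% for the overlap of 46.4% and 0.359% for that of 75.8%. For the promoter shares of 45.4% and 71.4% they gave 11.1% and 33.96%. Taking the strongest pooled peaks in place of the IDR-thresholded list changed nothing by construction, since both hold the same peaks, and is not counted. With the stronger 1152 peaks only, the rank correlation was 0.665, the promoter signal difference 2.98, the odds ratio of centres to arms 1.15 and the TGATAA ratio 0.832. Fewer peaks enter those tests, and beyond that the cause was not tested. Leaving out 1 replicate gave an X-linked odds ratio of 0.870 to 1.03, and stratifying by upstream distance gave 1.18. For TGACGTCA the fold was 1.14 to 2.00 without 1 replicate, 3.91 against shuffled windows and 2.5 against windows near genes without a peak. The signal difference of peaks with an AP-1 or CRE element was -0.898 to 0.330 without 1 replicate and 0.313 in the 100 bp window, against -0.877 in the 200 bp window. Assigning summits only to the nearest start left 3 depleted lists in place of 5. The cause was not tested for these. Among results that kept their side of the threshold, the ones that moved by over 1.5 times included the odds ratios of chaperones (7.57) and the proteasome (4.50) with the stronger 1152 peaks, and of cuticle collagens (0.162), F-box genes (0.220), neuropeptides (0.101) and chemoreceptors (0.0813) in the narrower promoter window. TGASTCA with its outer bases free gave the 1.42-fold. Of the called lists, 9 enriched and 2 depleted passed the threshold under every alternative run. For single lists, motifs and genes, 486 of 525 alternatives were the same, 14 lost the threshold, 2 gained it, 3 moved (the peak ranks of vhp-1, col-185 and clec-170 without replicate 1) and 20 reversed. Of those reversals TGATAA, given above, was the only one of a called result. With the stronger 1152 peaks TGTCAT turned to 0.986, and against shuffled windows to 0.842. Odds ratios of lists not called turned with the stronger 1152 peaks for reported targets (1.34), antimicrobial genes (0.113), body muscle (0.746), germline (1.83) and excretory, coelomocyte and glia markers (1.44). They turned in the narrower window for stress kinases (0.564) and excretory markers (1.01), and in the wider window for Ras and ERK (1.01), insulin and dauer (1.05) and body muscle (0.970). Stratifying turned histones (0.869) and insulin and dauer (1.03), the nearest start turned nuclear hormone receptors (1.13), and leaving ribosomal protein genes out turned germline (1.02). Without 1 replicate the range was 0.694 to 1.37 for antimicrobial genes, 0.562 to 2.04 for intestine and 0.972 to 1.05 for germline. Leaving out replicate 1 moved the odds ratio of ceh homeobox genes from 0.175 to 0.576, Ras and ERK from 0.640 to 0.311, glutathione transferases from 0.462 to 0.752 and hypodermis from 0.222 to 0.501, and leaving out replicate 2 moved pharynx from 0.544 to 0.248, glutathione transferases to 0.696 and hypodermis to 0.464, none past the threshold. The cause was not tested. No paired analysis was possible because there is 1 group. The unknown read depth limits what can be said of weak peaks, and absence from a list is not absence of binding.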

Other observations

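The tests of summits inside RNA genes, of motifs at single gene lists and of whether an AP-1 or CRE element marks most peaks of a list group, and the naming of the genes in this paragraph, were chosen after the data were seen. No list of tissue markers passed the adjusted threshold, with 8.42% of all protein-coding genes bound. Intestine markers had 3 of 20 bound (elt-2, the main intestinal GATA factor, act-5 and cpr-6), body muscle 3 of 28 (unc-60, unc-112 and unc-45) and neurons 3 of 28 (egl-21, snb-1 and ida-1). Pharynx had 1 of 21 (pha-4, the pharyngeal organ identity gene), germline 2 of 24 (mex-1 and cgh-1), excretory, coelomocyte and glia markers 1 of 15 (vha-8) and hypodermis 0 of 24. Among stress and detoxification lists, the redox list had 1 of 26 bound (wdr-23, a negative regulator of SKN-1), glutathione transferases 2 of 49 (gst-27 and gst-42), cytochromes 3 of 74 (cyp-33C8, cyp-33C6 and cyp-33C7), UDP-glucuronosyltransferases 1 of 67 (ugt-20) and antimicrobial genes 9 of 88. The call was gained for antimicrobial genes (odds ratio 0.113) and histone genes (2.53) among the stronger 1152 peaks, and for UDP-glucuronosyltransferases (0.122) in the wider promoter window. Among the regulator lists, also not past the threshold, nuclear hormone receptors stood at 21 of 269, ceh homeobox genes at 1 of 63 (ceh-38), bHLH factors at 1 of 25 (hlh-11), Ras and ERK genes at 1 of 18 (sem-5) and insulin and dauer genes at 2 of 26 (rheb-1 and akt-2). Histone genes had 9 of 72 bound, tRNA synthetases 5 of 32 (ears-2, mars-1, nars-1, aars-1 and aars-2) and nuclear rRNA genes 0 of 20.

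Some classes of RNA genes carried summits inside the gene. Within tRNA genes lay 53 of the 2305 summits, against a mean of 1.06 in 1000 random placements (50-fold, one-sided permutation p = 0.001, the smallest these allow). Within snoRNA genes lay 10 (9.09-fold, p = 0.001) and within snRNA genes 4 (11-fold, permutation p = 0.001). Within microRNA genes lay 2, against a mean of 0.617 (permutation p = 0.1), and within nuclear rRNA genes 0. These placements were uniform over each chromosome, without matching for activity or open chromatin. Whether JUN-1 binds at these RNA genes or they are recovered in any ChIP was not tested. Of the 111 bound snoRNA genes, 17 were reached only by peaks that also lay at a ribosomal protein promoter, and 51 only by peaks outside coding promoters. At the 56 ribosomal protein peaks, 0 summit windows held GAGAGAGA and 4 held CTGCGTCTC (7.14%).

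Of the 20 strongest peaks outside promoters 14 were on X, and the tests used the 20 strongest such peaks of X itself, with signals from 129 to 569. The ratio of median signal of X to autosomes was 0.924 at promoter peaks (bootstrap interval 0.843 to 1.01) and 1.09 outside promoters (0.996 to 1.21). These medians met the rule set in advance against a scale difference of the whole chromosome. They cannot exclude it, since the list is cut at a signal of 28.4 and a scale factor could mainly add weak X peaks. The ratio of 95th percentiles was 1.11 (0.888 to 1.38) and 2.31 (1.08 to 3.02), with intervals that overlap. X held 16.6% of all promoter peaks, 4 of the 10 strongest and 20 of the 100 strongest. A single replicate did not supply the strong X peaks outside promoters, because 100% of the 20 overlapped a peak among the 2305 strongest in each. As a hypothesis, some of the sites may be recruitment elements on X of the dosage compensation complex. The element TCGCGCAGGGAG with up to 2 mismatches stood in 10 of 20 summit windows. It stood in 2 of 40 windows 500 bp away and 8 of 218 summit windows of other X peaks outside promoters (larger of the exact p-values 0.000485). It stood also in 7 of 212 X promoter peaks (exact p = 0.0166 against windows 500 bp away), 10 of 789 autosomal peaks outside promoters (p = 0.00808) and 8 of 1066 autosomal promoter peaks (p = 0.920). With at most 1 mismatch it stood in 9 of the 20, 5 of the 218, 2 of the 212 X promoter peaks and 0 of the autosomal peaks. The strongest site, X:13700651-13701029, lacked the element, with 5 mismatches at the summit and in both windows beside it. The sites of signal 522 and 413 held it with 0 and 1 mismatches. Whether JUN-1 binds at the 20 sites or such sites are recovered in any ChIP stays open.

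Chance spacing as the source of the stretch without peaks at jun-1 was argued against by the replicate lists, where at most 0.161% of the peak-free stretches were as long, 0 of 1000 random draws in the surrounding 1 Mb were, and 2.15% (replicate 1) and 1.02% (replicate 2) of genes lay in such stretches. The pooled list argued less strongly, with 0.628% of stretches, 2 of 1000 draws and 7.08% of genes, and the sparser IDR-thresholded list not at all, with 34.1% of stretches, 676 of 1000 draws and 72.9% of genes. Unmappable sequence was argued against, as 95.4% of the 36-base words of the stretch occur once in the nuclear genome, compared with 92.5% along chromosome II. A candidate explanation is that extra copies of the locus on the jun-1 transgene raise the background of the control. The stretch spans 39.6 kb, within the 20 to 50 kb set in advance for a fosmid insert, and holds 8 whole genes including dnj-23, dyrb-1 and nlp-78. The explanation can hold only if the control came from animals with the transgene. Removal of the locus by the submitters stays open, since the length does not tell it from extra copies, and no biological explanation was tested.

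GAGAGAGA and CTGCGTCTC had the highest excess of the panel at the summits, while ribosomal protein, proteasome and chaperone genes were enriched for promoter peaks. The call for chaperones ended when each summit was given only to its nearest gene start. Base composition did not account for the motifs, since the lower excess of GAGAGAGA and CTGCGTCTC over shuffled windows was 4.11-fold. Over windows near genes without a peak the lower excess was 9.94-fold, so the motifs are not common to such windows in general. Those genes were drawn at random, without matching for activity or open chromatin, and 1027 of the peaks lay outside promoter windows. Sequence common to active promoters was therefore not excluded. At the ribosomal protein, proteasome and chaperone promoters, 1 of 89 peaks held an AP-1 or CRE element (1.12%, Wilson interval 0.199% to 6.09%), compared with 6.41% of the other peaks, so these exact elements do not mark most of those peaks. Whether they recruit JUN-1 at a minority of them cannot be told apart from background, with 1 peak against 0.562% of flanking windows (exact p = 1.00). At those promoters, degenerate elements, open chromatin, a protein partner and binding to other sequence were not tested.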
